A study of Bacillus subtilis PY79 with 41 samples.

How the data were processed

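Cells of Bacillus subtilis PY79 were grown in rich CH medium, in minimal S7 medium with sorbitol, or induced to sporulate, and were fixed with 3% formaldehyde for 30 min, per the labels' protocols. Hi-C used the restriction enzyme HindIII, and ChIP-seq used an antibody to mCherry, per the labels. Bowtie2 2.1.0 was used, per the submitters' processing notes, and the genome build is not given in the sources used here.

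The deposited Hi-C maps hold a fraction in each cell, and the authors' values in each row add up to nearly the same total, so that every bin has the same share of contact. The main diagonal and the neighbouring cells, 1210 cells in each map, are 0 in the deposited maps. Read counts cannot be had from these fractions, so the depth of each map is unknown and no counting interval was given. Balancing removes differences in visibility between bins, and it also means that a gain of contact at some distances lowers the shares elsewhere. The deposited ChIP-seq tables hold coverage at each of 4033459 positions as a signal that the authors did not scale to an input library in the tables used here. The mean coverage was 71.7 for mCherry-ParB and 62.2 for mCherry-ParB1(Vc), and 0.788% and 9.15% of positions were at 0.

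Each map was averaged with its transpose, bins with under 0.5 times the median total were left out (none were), and each cell was divided by the mean at its separation on the circle. The juxtaposition score at a position was the log2 of the mean, over arm distances of 100 to 1000 kb, of these ratios for pairs whose midpoint lay within 5 bins. Bin 1 starts at position 1, taken as 0 degrees, and degrees are the position over the chromosome length of 4033459 bp. The orientation rests on the hinge search over the whole chromosome, which placed the sites labelled 91 and -94 degrees at 95.9 and -99.8 degrees. The value near 91 degrees counts for less, since the search also gave 86.1 degrees in some libraries without ParB or SMC. The hinge was the bin with the highest score at 50 to 300 kb with a band of 2 bins. The short-range share, the extent (1.5 times expected) and the insulation score (10 bins on each side, boundary below -0.2) were computed from the same maps.

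The 39 Hi-C libraries were grouped by genotype, medium and temperature as the labels give them. Tests were limited by the design, as 2 of 37 groups had 2 libraries. The comparison of those 2 groups used an exact permutation test, and all comparisons used a size rule of 2 times the largest gap between libraries of the same condition over the named positions. The gap comes from 2 pairs of libraries, both in CH medium at 37 °C, and was not measured in other conditions. The paired libraries were not the same map deposited again, since 10.6% of wild type cells and 7.11% of delta-parAB cells held the same value. Cell by cell, the log2 ratios to the mean at separations of 100 kb or more correlated between paired libraries with r = 0.74 in wild type and 0.31 in delta-parAB. A small gap in the score therefore does not mean that the whole maps were alike.

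Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The score and the hinge search were tested on simulated maps, and the midpoint was found within 1 bin in 20 of 20 maps at each of 3 strengths. These maps held a single band without lean, no domains and a chosen depth. They do not show how the search performs on the deposited maps. Maps without a band gave a largest absolute score of 0.013, although they had no domains. The call rule, the tests and the alternatives not named as added were set before the data were examined. The alternatives were the width of the midpoint band, the median in place of the mean for the expected contact, nearer arm distances, balancing again, no bin filter, leaving out each replicate, and other thresholds for the remaining measures.

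Named items followed a rule set in advance, except that parS sites were those placed by the labels in place of sequence matches. The items were these sites, the 10 highest ChIP-seq windows over 20 kb from them, and the 10 deepest boundaries found in both wild type libraries. Only 4 such boundaries were found. A genome sequence and an annotation of the authors' build were not used here, so the planned search for parS sequences and the test of insulation at gene lists were not run, and windows and boundaries carry no gene names. Enriched windows are given as a percent of all windows. For both strains, parS sites were taken as the highest 1-kb window of mCherry-ParB within 10 kb of the position in the labels.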

Results

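The data were 39 Hi-C libraries and 2 ChIP-seq libraries from Bacillus subtilis PY79, a prototrophic laboratory strain with a single circular chromosome. Hi-C counts ligations between fragments that were crosslinked near each other, and each map gave the contact between bins of 10 kb around the whole chromosome. ParB binds the centromere-like parS sites near the replication origin, ParA is its partner ATPase, and SMC is the core subunit of condensin. The series title names the question, which is whether condensin brings together the DNA on either side of its loading site. The Hi-C libraries fell into 37 groups by strain, medium and temperature. Wild type and delta-parAB cells in rich CH medium at 37 °C had 2 libraries each, and each of the other groups had 1 library and therefore no replicate error. Positions are given in degrees from the origin at 0, with negative values on the left arm.

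Contact between the arms was summarised as a juxtaposition score. It is the log2 of observed over expected contact between loci at equal distances of 100 to 1000 kb on either side of a named position. A juxtaposition score of 0 equals the chromosome mean at the same separations. The largest gap between libraries of the same condition was 0.05, at +91 degrees in wild type, and a difference was called when it passed 0.11, which is 2 times that gap before rounding. Of 30 comparisons, 27 passed this size rule, 20 with a lower and 7 with a higher score. The depth of the Hi-C libraries is unknown, since the maps hold balanced values.

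**Figure D1:**
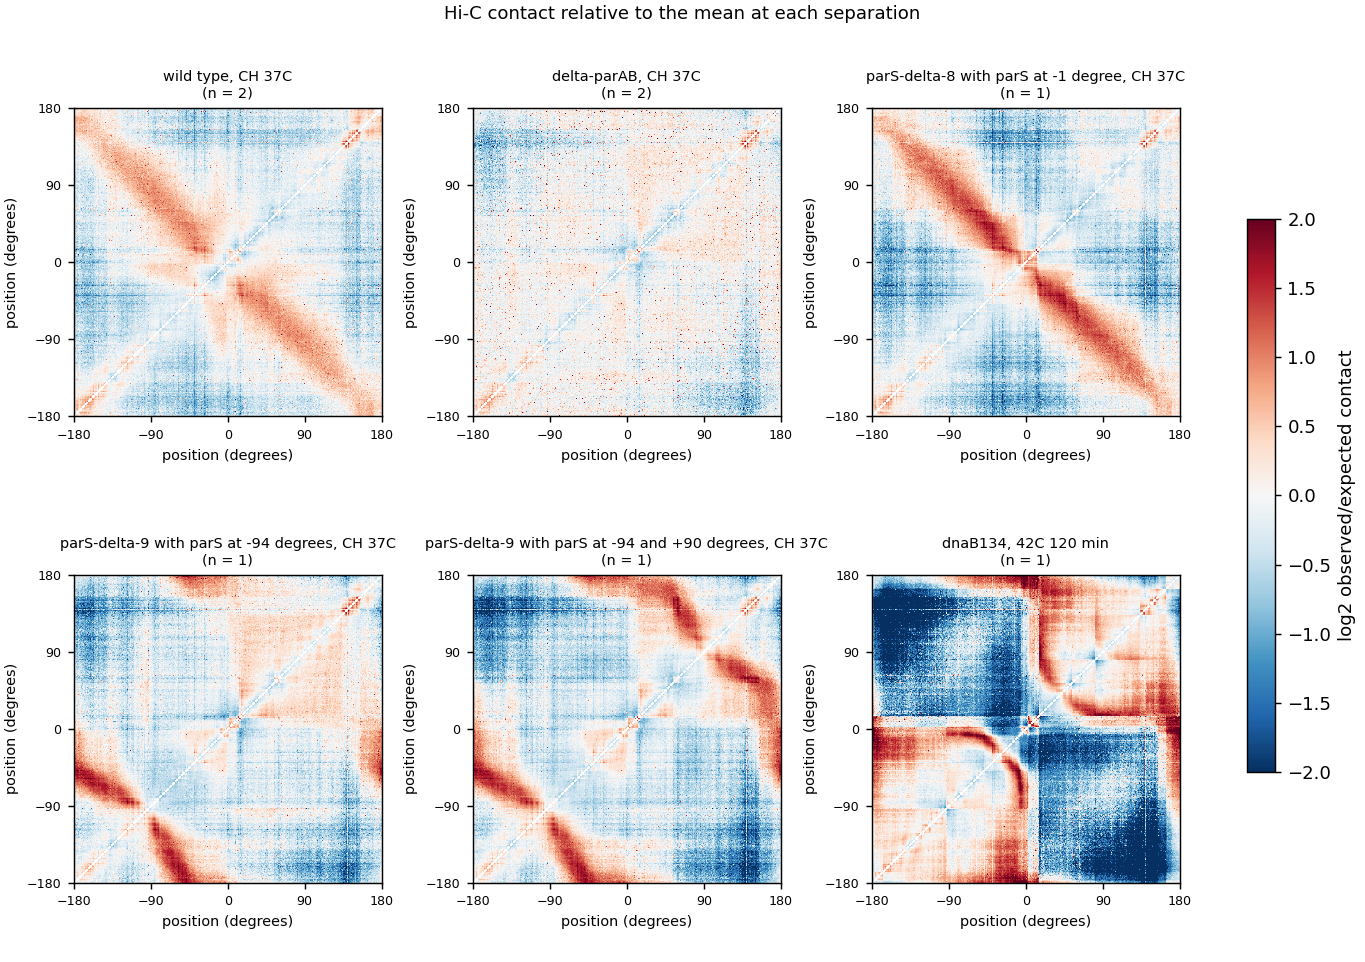
Hi-C contact relative to the mean at each separation, as log2 observed over expected, for 6 groups; both axes are chromosome position in degrees and n is the number of libraries averaged. The band running across the main diagonal from the origin in wild type, where the score at -1 degree was 0.81, is not seen in delta-parAB, where it was 0.05, and it starts at -94 degrees where a parS site was placed there.

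The first comparisons asked whether the contact between the arms needs the ParABS system. In wild type cells in CH medium, loci on opposite arms met 1.75 ± 0.0174 (SD, n = 2) times as often as the mean at their separation. In delta-parAB cells the value was 1.03 ± 0.00672 (SD, n = 2), and the score fell by 0.76. The scores were 0.81 ± 0.014 and 0.05 ± 0.0094 (SD, n = 2 each). The groups did not overlap, and the exact two-sided permutation test gave p = 0.33, the smallest p that 2 against 2 libraries allow. Nothing in the labels says whether the libraries came from separate cultures. At its floor, this p shows only that the groups did not overlap and measures no spread.

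Contact between the arms also fell without ParB alone and without its binding sites. The score at -1 degree was 0.05 in delta-parB, in parS-delta-9, which lacks the named parS sites including yhaX at +91 degrees, and in the strain whose ParB carries G77S. Each was lower than wild type by about the same amount, with differences of -0.76, -0.75 and -0.75. Without ParA the score was 0.68, a difference of -0.12 from wild type. The delta-parA call rested on the setting, since it was not kept with a midpoint band of 2 bins, with the expected contact taken as the median or at arm distances of 50 to 300 kb.

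The medium was compared in wild type and delta-parAB cells. In minimal S7 medium with sorbitol at 37 °C the score was 0.71 in wild type and 0.04 in delta-parAB, a difference of -0.66. Wild type in S7 differed from wild type in CH by -0.10, which was within the call limit. Without wild type replicate 2 that difference was -0.11 and passed the limit, and its direction turned with the expected contact taken as the median (0.049) and at arm distances of 50 to 300 kb (0.15).

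A ParB fused to the red fluorescent protein mCherry was set beside wild type, and beside a mCherry fusion that the labels name ParB1(Vc). The strain with mCherry-ParB had a score of 0.84 at -1 degree and differed from wild type by 0.03, within the call limit. The strain with mCherry-ParB1(Vc) had a score of 0.05, lower than mCherry-ParB by 0.79 (difference -0.79).

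**Figure D2:**
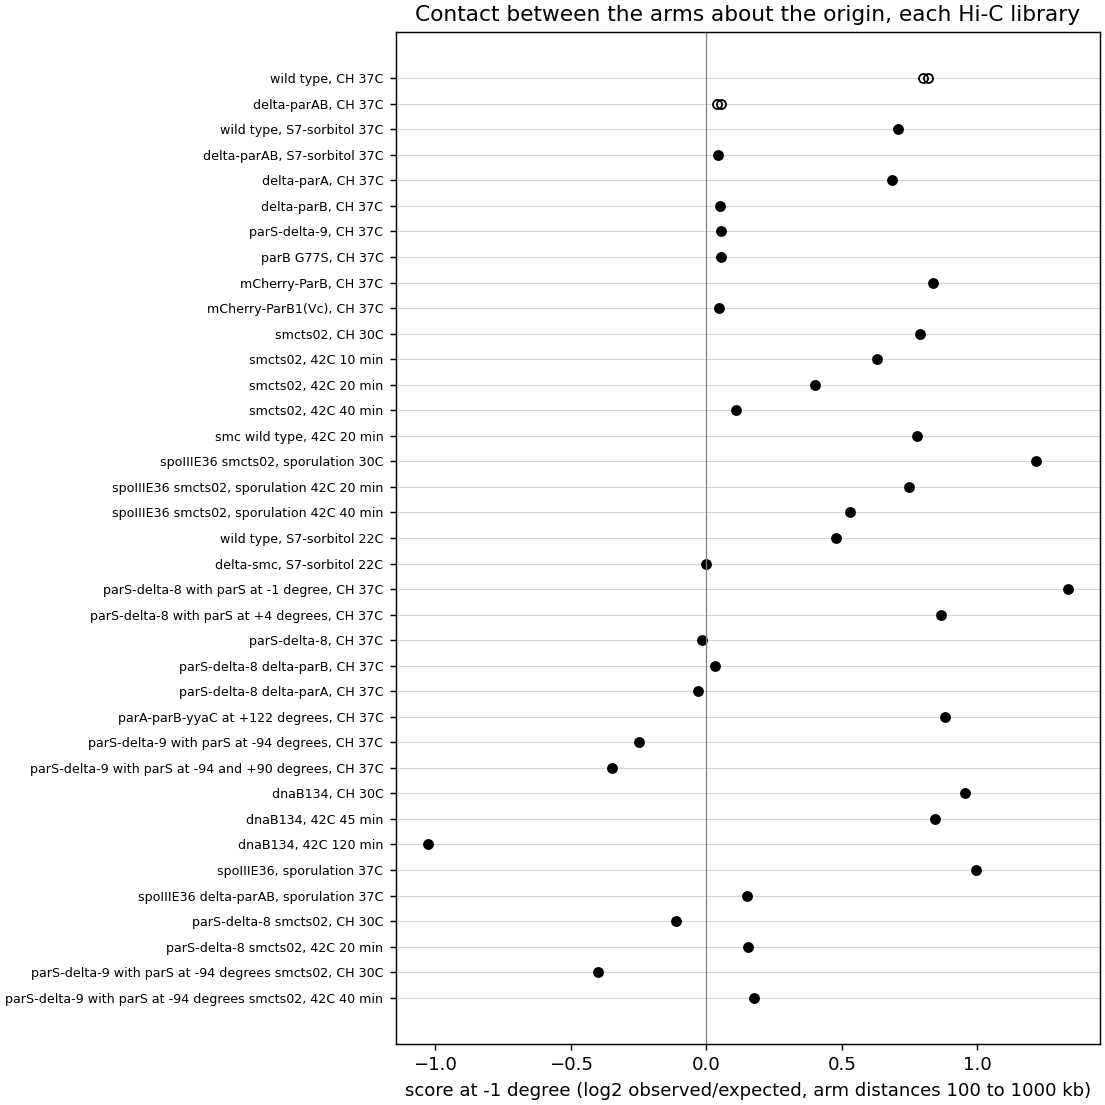
Juxtaposition score at -1 degree (horizontal axis, log2 observed over expected) for each Hi-C library, by group; open points are the 2 libraries of a group with replicates and filled points are single libraries. Wild type libraries in CH medium lie near 0.81, delta-parB and parS-delta-9 near 0.05, and dnaB134 after 120 min at 42 °C at -1.03.

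The part of condensin was examined in strains with smcts02 or without smc. The strain smcts02 carries a temperature-sensitive SMC, as its name gives it. At 30 °C its score at -1 degree was 0.79, and after 10, 20 and 40 min at 42 °C it was 0.63, 0.40 and 0.11. The differences from 30 °C were -0.16, -0.39 and -0.68. The smc wild type strain shifted to 42 °C for 20 min had a score of 0.78, and smcts02 at the same time lay below it (difference -0.38). That strain was not used at 10 or 40 min. In S7 medium at 22 °C the wild type score was 0.48 and the delta-smc score 0.00043 (difference -0.48). The call at 10 min was not kept with the expected contact taken as the median or at arm distances of 50 to 300 kb.

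The values in smcts02 were lower at 42 °C in each of 4 ranges of arm distance. At -1 degree, observed over expected contact at arm distances of 50 to 250 kb was 1.18 at 30 °C and 0.548 after 40 min at 42 °C. At 250 to 500 kb it went from 1.77 to 1.06, at 500 to 1000 kb from 1.85 to 1.25, and at 1000 to 1800 kb from 1.75 to 1.14.

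Sporulating cells were examined in strains with spoIIIE36, whose DNA translocase does not move the chromosome. After 150 min at 37 °C the score at -1 degree was 1.00 with the par genes and 0.15 in delta-parAB, a difference of -0.85. With smcts02 the score was 1.22 after 190 min at 30 °C. It was 0.75 when the last 20 min were at 42 °C and 0.53 when the last 40 min were, with differences of -0.47 and -0.69. No sporulating library with wild type smc at 42 °C was used here, so a heat effect and an SMC effect were not separated.

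Strains whose labels place 1 parS site at different points were compared, to ask whether the position of the site sets where the arms meet. In the parS-delta-8 background with a wild type parS in parB at -1 degree, the score there was 1.33, against 0.05 in parS-delta-9, a difference of 1.28. With a wild type site in metS, the methionyl-tRNA synthetase gene, at +4 degrees, the score at +4 degrees was 1.10, against 0.02. The strain parS-delta-8, which keeps the site in yhaX at +91 degrees, had a score of 0.38 at +91 degrees against 0.19 in parS-delta-9, a difference of 0.19. The site inserted at -94 degrees gave 0.65 there against 0.11. The labels do not state outright whether the strains with sites at -1 and +4 degrees lack the site at +91 degrees, where their scores were -0.36 and -0.34. These scores cannot tell, since the wild type libraries in CH, which keep that site, scored -0.32 and -0.37 there. The call at +91 degrees was not kept with the expected contact taken as the median.

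The centre of each band was also located without using the label, as the bin with the highest score over arm distances of 50 to 300 kb. In the 4 strains whose labels place 1 site it lay at -2.54, 6.69, 95.9 and -99.8 degrees, for labelled positions of -1, 4, 91 and -94 degrees. All 4 lay within 10 degrees of the label. In both wild type libraries the same search gave 174.5 degrees, near the terminus. It gave 86.1 degrees, also near 91, in delta-parAB library 1 in CH and in delta-parAB and delta-smc in S7. Contact there was 1.20, 1.36 and 1.26 times expected, against 1.54 times at 95.9 degrees in parS-delta-8. For +91 degrees, closeness to the label alone therefore does not locate the site. At 100 to 1000 kb the centres in the 4 strains lay at -1.65, 7.59, 101.3 and -107.9 degrees, and 2 of the 4 were within 10 degrees. Contact at -1 degree in wild type stayed below 1.5 times the expected value at 50 kb, so its extent by that rule was 0 kb. Farther out it was above 1.5 times in both libraries, with 1.84 and 1.78 times at 250 to 500 kb and 1.585 and 1.598 times at 1000 to 1800 kb. With the site at -1 degree the extent reached 1770 kb on each arm, and with the site at +4 degrees 1500 kb. Both became 0 kb at 2.0 times the expected contact, although contact was 2.73 and 2.38 times at 250 to 500 kb. With sites at +91 and -94 degrees the extent was 0 kb, since contact was below 1.5 times at 50 kb, although at -94 degrees it was 1.60 times at 50 to 250 kb and 1.70 times at 250 to 500 kb.

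With sites at both -94 and +90 degrees, the highest contact within 20 degrees of each, at arm distances of 50 to 300 kb, lay at -99.8 and 95.1 degrees. The score was 0.77 at -94 degrees and 0.81 at +90 degrees, against 0.11 and 0.19 in parS-delta-9 (differences 0.66 and 0.63). At -1 degree the same library had a score of -0.35. An insertion of parA, parB and yyaC in ykoW at +122 degrees gave -0.11 there against -0.29 in wild type. The difference of 0.18 was not kept with the expected contact taken as the median. Over arm distances of 50 to 300 kb, the highest observed over expected contact within 20 degrees of +122 degrees was 1.40 at 128.1 degrees in this strain, against 0.958 and 0.939 in the wild type libraries. Its score at -1 degree was 0.88.

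**Figure D3:**
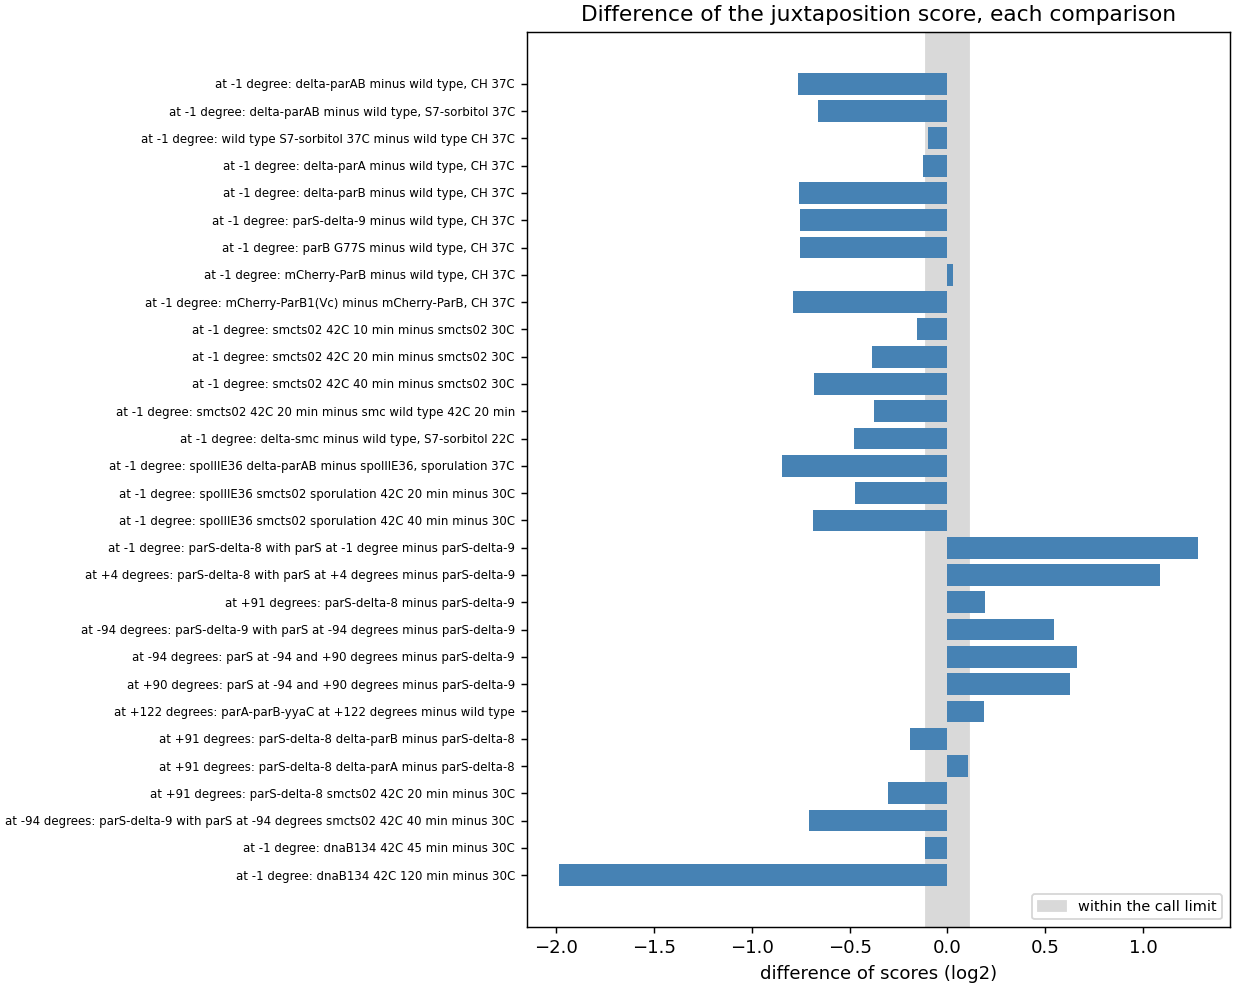
Difference of the juxtaposition score (horizontal axis, log2) for each of the 30 comparisons, with the position and the groups named on the vertical axis; the grey band marks the call limit of 0.11 on either side of 0. The differences run from -1.98 in dnaB134 after 120 min at 42 °C to 1.28 for the site at -1 degree.

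The bands at +91 degrees, a site that parS-delta-8 keeps, and at the inserted site at -94 degrees were examined in strains without parB or parA or with smcts02. The amount of SMC was not measured here. In parS-delta-8, removing ParB lowered the score at +91 degrees from 0.38 to 0.19 (difference -0.19). Removing ParA gave 0.48 (difference 0.10), within the call limit, and passed its limit with the highest score within 20 degrees (0.18), an alternative chosen after seeing the data. With smcts02 the score at +91 degrees was 0.52 at 30 °C and 0.22 after 20 min at 42 °C, a difference of -0.30. With the site at -94 degrees and smcts02, the score there was 0.76 at 30 °C and 0.05 after 40 min at 42 °C, a difference of -0.71. No library of these site strains with wild type smc at 42 °C was used, so heat and SMC effects were not separated. At +91 degrees the call for ParB was not kept with the expected contact taken as the median, nor were those for ParB and smcts02 at arm distances of 50 to 300 kb.

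DnaB is needed to start replication, and dnaB134 is marked temperature sensitive in the labels. Its score at -1 degree was 0.96 at 30 °C, 0.84 after 45 min at 42 °C and -1.03 after 120 min. The differences from 30 °C were -0.11 and -1.98. No strain with wild type dnaB was used at 45 or 120 min, so heat and DnaB effects were not separated. The call at 45 min was not kept with a midpoint band of 2 bins, with the expected contact taken as the median, at arm distances of 50 to 300 kb or with the highest score within 20 degrees. At 120 min the score was 1.03 at +91 degrees and 0.91 at -94 degrees. Loci scored there lie mostly on the same chromosome arm, so these 2 values do not show contact between the left and right arms. The share of all contact that joined the left and right arms was 43.5% at 30 °C, 41.7% at 45 min and 14.7% at 120 min, against 44.2% ± 0.151 (SD, n = 2) in wild type.

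The share of contact at 20 kb or more that lay at 20 to 200 kb was used as a measure of the short range. Being a share, it also rises when contact at longer range falls, so a rise need not mean compaction. The share was 24.6% ± 0.178 in wild type and 23.3% ± 2.57 in delta-parAB (SD, n = 2 each). The limit from the same size rule was 7.26 percentage points. In smcts02 the share rose from 25.3% at 30 °C to 33.0% after 40 min at 42 °C, a difference of 7.61 points, and in dnaB134 from 27.3% to 37.5% after 120 min, a difference of 10.2 points. No other comparison passed the limit. Between smcts02 and smc wild type, both after 20 min at 42 °C, the difference was 7.24 points (31.2% against 24.0%), just short of it. The limit came from the delta-parAB pair, whose gap was 3.63 points, against 0.252 in the wild type pair. The share of contact that joined the left and right arms fell in both comparisons that passed, in smcts02 from 43.8% to 31.0%.

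Domain boundaries were sought as local minima of contact across a bin edge. The wild type libraries held 7 and 4 boundaries, and 4 were found in both within 1 bin. They lay at -17.3, 53.5, 15.2 and 32.1 degrees, from the deepest to the shallowest by mean insulation. The boundaries at 53.5 and 15.2 degrees were found in 26 of the 39 libraries, and those at -17.3 and 32.1 degrees in 9. Of the 4, 2 were found in both delta-parAB libraries.

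ChIP-seq with an antibody to mCherry measured where the ParB fusions bound, with 1 library per strain and no input library used here. Coverage within 1 kb of the site at -1 degree, in the window at 4023001 to 4024000, was 501.4 times the median window for mCherry-ParB and 130.7 times for mCherry-ParB1(Vc). At +4 degrees, in the window at 48001 to 49000, it was 121.4 and 18.8 times. That window is the highest of mCherry-ParB, and at the highest of mCherry-ParB1(Vc), at 50001 to 51000, an alternative chosen after seeing the data, the value for mCherry-ParB1(Vc) was 53.2 times. At +91 degrees, in the window at 1020001 to 1021000, it was 12.1 and 20.1 times. The median window within 30 degrees of the origin was 82.3 for mCherry-ParB and 64.2 for mCherry-ParB1(Vc), against 7.52 and 7.07 near the terminus. Against the median within 100 kb, an alternative chosen after seeing the data, the folds were 66.9, 22.2 and 11.2 for mCherry-ParB and 17.1, 4.55 and 15.5 for mCherry-ParB1(Vc), in the same order of sites.

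Windows at 5 times the median or more made up 7.31% of the 4033 windows for mCherry-ParB and 8.75% for mCherry-ParB1(Vc). Of these, 68 and 62 windows lay within 20 kb of a site that the labels place. Over the local median, chosen after seeing the data, the shares of all windows were 2.78% and 3.05%. Among windows over 20 kb from those sites, the highest for mCherry-ParB was at 3970001 to 3971000 (-5.62 degrees, 394.96 times the median) and for mCherry-ParB1(Vc) at 3964001 to 3965000 (-6.16 degrees, 393.80 times). All 10 of the highest windows in each strain lay between -27.4 and -4.73 degrees. The labels name further parS sites by gene that were not placed here. Windows over 20 kb from the placed sites may therefore still lie at parS.

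**Figure D4:**
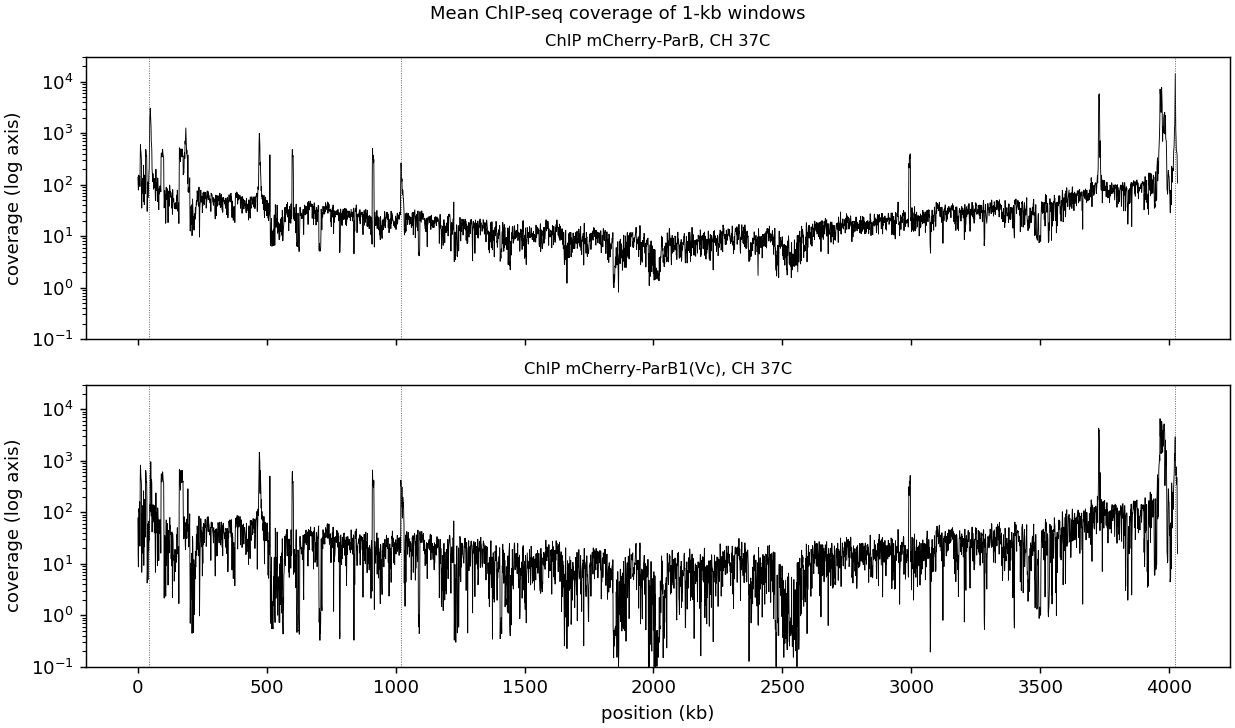
Mean ChIP-seq coverage of 1-kb windows (vertical log axis, coverage per base) along the chromosome (horizontal axis, kb) for the 2 strains; dotted lines mark the sites that the labels place at -1, 4 and 91 degrees. The highest window is at the site at -1 degree for mCherry-ParB, 722 times the median, and at -6.16 degrees for mCherry-ParB1(Vc), 393.80 times.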

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

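All tests in this part were chosen after the result was seen. The share of contact at 20 to 200 kb moved in opposite directions with the shift of smcts02 to 42 °C, up in growing cells and down in sporulating cells. In growing cells it changed by 5.21, 5.88 and 7.61 percentage points after 10, 20 and 40 min, by 6.59 points in parS-delta-8 after 20 min, and by 4.32 points with parS at -94 degrees after 40 min. In sporulating cells it changed by -2.46 points after 20 min and -3.62 points after 40 min. The difference between growth and sporulation was not tested, there was 1 library per condition, and of these changes the one of 7.61 points passed the limit of 7.26.

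The delta-parAB libraries alone differed by 3.63 points. Ligation between unrelated fragments, which adds an even background to a map, may give such shifts. Mixing the steeper curve of each pair with an even background left residuals of 0.854 to 3.00 times that of the delta-parAB pair, the largest in parS-delta-8. In sporulation the largest was 1.03 times. In growth the 42 °C curve was the steeper, so the fit put the background in the 30 °C library. Background would lower the juxtaposition score there, yet each growing pair scored lower at 42 °C (differences -0.16 to -0.71). This argues against background as the only difference in those pairs. The share was 25.35% in smcts02 at 30 °C, 24.6% in wild type and 24.0% in smc wild type after 20 min at 42 °C. In sporulation the fit put the background at 42 °C, where the score was lower. Whether background moved the share cannot be told here, because the bound of 2 was met in some pairs and passed in others. A biological difference between growth and sporulation stays open and was not tested.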

How the results depend on the processing

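Of 30 juxtaposition differences, 21 kept their call under every alternative run and 9 did not, and 0 called differences reversed. Wild type in S7 against CH, which was not called (-0.10), turned to 0.049 with the median and 0.15 at 50 to 300 kb. The alternative that takes the highest score within 20 degrees, the local ChIP-seq background and the highest ChIP-seq window of each strain were chosen after seeing the data. Calls were lost as follows, and the cause was not tested beyond the call limit, which rose from 0.11 to 0.13 with a band of 2 bins, 0.27 with the median and 0.30 at 50 to 300 kb. For delta-parA the differences were -0.13, -0.16 and -0.039 under these 3 settings, and for dnaB134 at 45 min -0.12, -0.15 and -0.034, and -0.055 with the highest score. With the median, smcts02 at 10 min gave -0.22, parS-delta-8 0.26, the +122 insertion 0.19 and delta-parB in parS-delta-8 -0.25. At 50 to 300 kb, smcts02 at 10 min gave -0.24, delta-parB in parS-delta-8 -0.30 and smcts02 in parS-delta-8 -0.24. Calls were gained for delta-parA in parS-delta-8 (0.18, highest score) and for wild type in S7 against CH, which ranged from -0.11 to -0.091 when each wild type library was left out. Balancing again moved each difference by at most 0.001 and the bin filter removed nothing, so neither tests stability. The hinge count went from 4 to 2 at 100 to 1000 kb, the wild type short-range share from 24.6% to 14.8% at 10 to 100 kb, and the boundary count from 5.5 to 12.5 with 5-bin flanks and 3 at -0.3. ChIP-seq folds for mCherry-ParB at -1, 4 and 91 degrees became 136.8, 33.1 and 3.30 over the mean of windows and 148.5, 75.5 and 5.99 within 5 kb, and over the local median 66.9 and 22.2 at the first 2 sites. For mCherry-ParB1(Vc) they became 35.1, 5.05 and 5.40 over the mean, 65.9 and 10.1 within 5 kb at -1 and 91 degrees, and 17.1 and 4.55 over the local median at -1 and 4 degrees. At 4 degrees the value went from 18.8 to 53.2 at that strain's own highest window. Enriched windows of mCherry-ParB and mCherry-ParB1(Vc) made up 3.92% and 4.07% at 10 times the median, and 2.78% and 3.05% over the local median. The extents of 1770 and 1500 kb with sites at -1 and 4 degrees became 0 kb at 2.0 times the expected contact, and wild type was 0 kb at both thresholds. By the rule an extent is 0 kb when contact at 50 kb is below the threshold. At 250 to 500 kb contact was 2.73 and 2.38 times with those sites and 1.84 and 1.78 times in the wild type libraries. The insulation test at gene lists was not run. No paired analysis was run. The labels number 1 library in each group with replicates and leave the other without a number, so a pairing by that number would be an assumption.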

Other observations

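All tests in this part were chosen after the result was seen. The 2 ParB fusions differed along the chromosome, in regions found by a local background chosen after their values were seen. At 4020001 to 4027000 the log2 ratio of mCherry-ParB1(Vc) to mCherry-ParB was -1.29 and at 45001 to 55000 it was -1.89. It was below 0 in 4 of 17 regions and above 0 in the other 13, where it ran from 0.42 to 1.10. Of these 13, 6 entered through mCherry-ParB1(Vc) alone, which favours a ratio above 0, and in the one with 0.42 the highest local fold was lower in mCherry-ParB1(Vc) (54.1 against 63.7). At 469001 to 480000 it was 0.79 and at 1020001 to 1031000 it was 1.06. Each library was scaled by its own median window. In the Hi-C maps, the highest bin within 20 degrees of -1 degree at 50 to 300 kb lay at -7.00 degrees in both wild type libraries in CH. The highest bin of the whole chromosome in these 2 libraries lay at 174.5 degrees. Within 20 degrees of -1 degree it lay at -5.22 degrees in delta-parA. The same bin was highest there in wild type in S7 at 37 °C and in smc wild type after 20 min at 42 °C, so it was not particular to delta-parA.

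Bands from sites away from -1 degree leaned toward the terminus, and at -1 degree the displacement at 600 to 1000 kb was 30 kb in both wild type libraries and 0 kb with the site at -1 degree. At 100 to 300 kb it was 70 kb in both wild type libraries and 30 kb with the site at -1 degree. It was 20 kb there with the site at +4 degrees, 60 kb in parS-delta-8 and 70 kb with the site at -94 degrees. A near displacement was therefore not particular to sites away from -1 degree. In parS-delta-8 it was 120 kb at 300 to 600 kb and 60 kb at 600 to 1000 kb, so it did not grow steadily. At arm distances of 600 to 1000 kb, the centre lay 50 kb on the terminus side with the site at +4 degrees (80 kb after the division below), 60 kb in parS-delta-8, 110 kb there without ParA, and 180 kb with the site at -94 degrees. An offset of the bin coordinates would move both arms the same way, and the signed displacement at +90 and +91 degrees minus that at -94 degrees was 25 bins, which argues against it. Uneven background contact along the arm may account for part: after division by the parS-delta-9 map the displacement was 110 to 120 kb at +91 degrees in 3 libraries and 160 to 180 kb at -94 degrees in 3 libraries, and the smallest was 5 bins (50 kb), at +90 degrees in the strain with 2 sites. The bound was first written as 5 bins or more, which this value met, and was made strict after that was seen, so this stays open and no biological explanation was tested.

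An even ligation background could also lower the juxtaposition score, and it would lower the share of contact at 20 to 200 kb with it. At the background each loss would need, the control's share lay below the mutant's by 11.1 to 14.6 points, against a limit of 7.26, in all 6 losses of growing parAB, parB and parS mutants at -1 degree, which argues against background as the whole cause there. In growing smc mutants at -1 degree, 3 of 5 losses passed that limit. These were smcts02 after 20 and 40 min (11.4 and 19.2 points) and after 20 min against smc wild type (12.3 points). The excess was 6.16 points after 10 min and 7.06 in delta-smc, so background stays open for that class as a whole. At +91 and -94 degrees 2 of 3 losses passed, both in smcts02 (13.1 and 21.55 points). Removing ParB at +91 degrees gave 6.86 points, so background stays open for that class too. In sporulating cells none of 3 losses passed the limit (3.38 to 6.85). The background fitted to their contact curves was 27.7%, 11.3% and 15.9%, where 77%, 32% and 50% were needed, so it stays open there too. In delta-parA (-1.85, with 11.9% fitted and 2% needed) background may account for the difference. Growing and sporulating cells were set apart after these values were seen, and 2 earlier versions on the score, first with delta-parA and dnaB134 pooled with the others and then without them, were replaced after their results were seen because the fitted background was 0 in 4 of 6, 5 of 5 and 3 of 3 losses of the growing classes, which left the outcome there to the call itself.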
